A study of Mus musculus with 12 samples.

How the data were processed

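RNA was measured by sequencing in 12 cultures of mouse pancreatic ductal adenocarcinoma cells (cell line KPshp53, with mutant Kras). The labels place them in 4 groups of 3 biological replicates: control hairpin untreated (shCTR_NT), control hairpin treated (shCTR_AZA), Trp53 hairpin untreated (shp53_NT) and Trp53 hairpin treated (shp53_AZA). Treated cells had received 5-Aza-2′-deoxycytidine (AZA), an inhibitor of DNA methyltransferases, for 48 hours. Per the labels' protocols, RNA was extracted with the RNeasy kit and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA.

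The deposited table held 27179 genes with Entrez identifiers and coordinates, 1 column of values per sample, and the authors' own comparisons. The submitters' processing notes name the mm10 assembly, BWA, STAR and DESeq2, without versions or roles. The counting program, annotation release and strand setting were not given in the sources used here, so overlapping, antisense and near-identical genes were treated as uncertain. The deposited per-sample values are a normalized score: whole numbers that, from their own pattern, are read counts divided by a size factor per sample and rounded, and not raw counts. Median-of-ratios size factors of these values lay between 0.9993 and 1.0026. The size factor of each library was recovered from the rounding pattern of its low values, with an error of at most 0.0003 on simulated counts. The deposited log2 fold changes are shrunken, per the file headers, and the deposited adjusted p-value columns cover the 4 comparisons of 2 groups and no interaction. A symbol was missing for 847 genes and 2 symbols occurred more than once.

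Because the table held normalized values, differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1). A gene was tested when its mean reached 10 in at least 1 group, which left 14297 genes. All 12 samples entered 1 fit with a coefficient per group and no replicate block, leaving 8 residual degrees of freedom. The 5 contrasts were the AZA effect in shCTR, the AZA effect in shp53, the shp53 effect without treatment, the shp53 effect under AZA, and the interaction, which is the AZA effect in shp53 minus that in shCTR. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and the threshold was an adjusted p of 0.05. On the log2(value + 1) scale the fold change of a gene with values near 0 is understated. A group whose 3 values summed to 3 or less is described by its levels, with no fold change.

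Fixed gene lists, 25 in number, were tested per contrast with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. They covered p53 targets, G1/S and replication, G2/M and mitosis, germline genes, imprinted genes, the interferon response, antigen presentation, the serine and one-carbon pathway, the methionine cycle, the integrated stress response, the DNA methylation machinery, heterochromatin, R-loop factors, homologous recombination, NF-kB and inflammation, epithelial and mesenchymal genes, glycolysis, the tricarboxylic acid cycle, cholesterol synthesis and mitochondrially encoded genes. The other lists held markers of acinar cells, fibroblasts, leukocytes and endothelial cells. The list of serine and one-carbon genes shares 7 of its 22 members with other lists, most of them with the list of the integrated stress response. R-loop factors share 5 of 30 tested members with other lists, and homologous recombination 5 of 27. The series title names metabolic regulation and R-loops, so the lists for these subjects follow the study's own interest. Members of a list that passed the threshold were counted over all genes and with p-values adjusted over the list alone. Camera compares a list with the other tested genes, and a list is named as called by camera alone. As planned, limma's fry was also run, which asks whether a list changed without regard to other genes. A list not called can therefore hold many changed members, and several such lists passed fry.

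The groups, the test, the lists and the rule for named genes were fixed before the data were examined. That rule takes Trp53, then, per contrast, the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among genes past the threshold. These needed a mean of at least 100 in the higher group, a symbol that is not a clone or model name, and no overlap between the replicates of both groups (not for the interaction). From each list, up to 4 members with the smallest adjusted p could be named.

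The procedure was tested on simulated data with 200 of 13878 genes changed by AZA in shCTR. It made 190 calls, of which 9 were false (4.74%). It called 84% of genes changed 1.25-fold, 80% of those changed 1.5-fold, 100% at 2-fold and 98% at 4-fold, all with the right sign. For the unchanged comparisons of AZA in shp53 and of untreated shp53 with untreated shCTR, limma made 0 calls each, and 0 of 20 unchanged lists were called. The simulation gave every gene the same dispersion (0.000224), scaled the libraries without error and changed few genes. Its error rates may therefore not carry over to these data, where most genes were called.

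Estimated read totals, from the recovered size factors, ran from 26.6 to 36.7 M reads per library, and normalized totals from 29.9 to 33.4 M. Between 2 replicates of a group, the median squared difference was 1.2 to 2.07 times that of counting noise alone. The p-values measure this spread between cultures. The labels name no separate knockdown lines per hairpin, so a spread between such lines is not measured. Alternatives were quantile normalization, no filter and a stricter filter (mean of 100), pseudocounts of 0.5 and 5, only the 6 samples compared, the replicate number as a block, thresholds of 0.01 and of an absolute log2 fold change of 1, the authors' deposited comparisons, and leaving out each library. Scaling to equal totals was added after seeing the data, as was the use of both scalings for the gene lists. No sample was left out of the fit.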

Results

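RNA sequencing compared KPshp53 cells, derived from a mouse pancreatic ductal adenocarcinoma with a mutant Kras allele, that carried a control hairpin (shCTR) or a hairpin against Trp53 (shp53). Each was left untreated (NT) or treated for 48 hours with 5-Aza-2′-deoxycytidine (AZA), which traps DNA methyltransferases and lowers DNA methylation. Every one of the 4 groups had 3 biological replicates. Estimated depth was 34.4, 36.4 and 34.5 M reads in shCTR_NT, 30.6, 32.7 and 33.7 M in shCTR_AZA, 33.5, 36.7 and 31.5 M in shp53_NT, and 26.6, 27.5 and 27.1 M in shp53_AZA. The shp53_AZA libraries were thus the shallowest, and they also had the highest share of mitochondrially encoded transcripts, between 2.76% and 2.92%, compared with 2.00% to 2.36% in the other 9 libraries. The number of genes with a value above 0 lay between 15576 and 16223 in untreated and between 17108 and 17412 in treated libraries. Levels below are normalized read counts, given as mean ± SD (n = 3), and p-values are Benjamini-Hochberg adjusted values of limma or, for gene lists, of camera.

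Was Trp53 lowered by its hairpin? Trp53 (gene 22059, chromosome 11, 69580359 to 69591873, plus strand, mm10) stood at 2031, 1998 and 2007 in the shCTR_NT replicates, 2588, 2648 and 2632 in shCTR_AZA, 382, 368 and 359 in shp53_NT, and 390, 428 and 417 in shp53_AZA. The hairpin left 18.4% of the level in untreated cells (log2 fold change -2.44, SE 0.04, adjusted p = 3.57e-23) and 15.7% under AZA (-2.67, adjusted p = 1.67e-23). AZA itself raised Trp53, by 0.38 on the log2 scale in shCTR and by 0.15 in shp53. An exact permutation test of each of these 4 comparisons gave p = 0.1 (two-sided), the smallest value that 3 against 3 samples allow. The Trp53 level of every library matched its hairpin label.

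**Figure D1:**
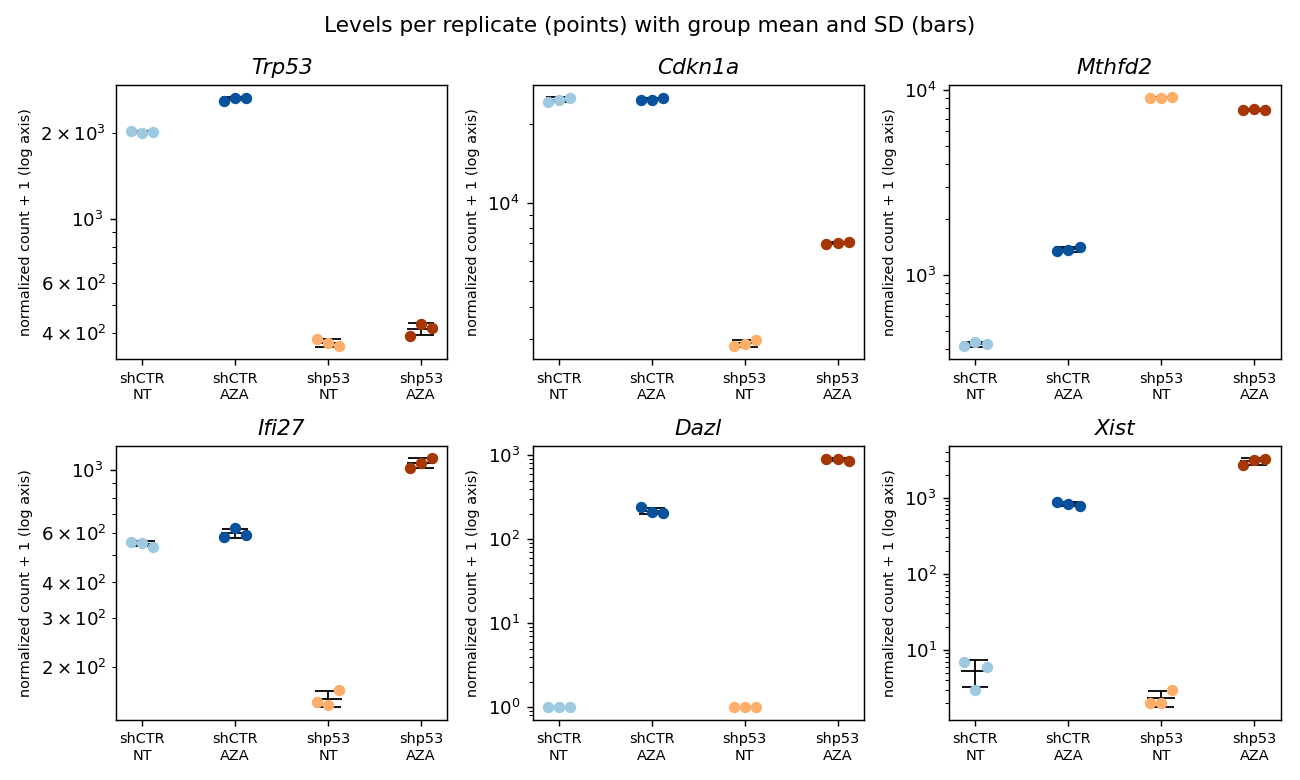
Normalized read counts plus 1 (log axis) of 6 genes in the 4 groups; points are replicates, and the horizontal bars are the group mean and SD (n = 3). Trp53 and Cdkn1a are lower in shp53, Mthfd2 is higher in shp53, and Dazl and Xist are near 0 without AZA and highest in shp53_AZA, at 894 ± 30.3 and 2990 ± 304.

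The first comparison asked how untreated cells with the Trp53 hairpin differed from control cells. The labels do not state whether shCTR and shp53 cells come from separate infections, so differences between them other than p53 stay open for every shp53 effect and for the interaction. Genes activated by p53 fell steeply with the hairpin, while genes of the cell cycle, DNA repair and the serine and one-carbon pathway rose. Among the p53 targets, 29 of 35 fell and 5 rose (camera adjusted p = 6.28e-09). Cdkn1a, the cyclin-dependent kinase inhibitor p21 (gene 12575, chromosome 17, 29090986 to 29100722), went from 24772 ± 542 to 2889 ± 80.4, and Mdm2, the ubiquitin ligase that degrades p53, from 41905 ± 1170 to 3866 ± 74.1. Btg2, an antiproliferative factor, changed by -4.17 on the log2 scale (SE 0.02) and Ccng1, cyclin G1, by -3.40 (SE 0.02).

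Proliferation genes moved the other way. All 25 tested genes of G2/M and mitosis rose (adjusted p = 3.1e-14). Top2a, the DNA topoisomerase of dividing cells, rose from 1186 ± 50.3 to 15732 ± 156, and the mitotic checkpoint kinase gene Bub1b by 3.67 on the log2 scale (SE 0.03). Of the G1/S and replication genes, 26 of 28 rose and 1 fell (adjusted p = 8.79e-09), with the replicative helicase subunits Mcm3 at 599 ± 4.73 and 3496 ± 47 and Mcm5 at 307 ± 22.1 and 1992 ± 42.2 in shCTR and shp53. Homologous recombination and Fanconi anaemia genes rose in 24 of 27 cases and fell in 3 (adjusted p = 5.86e-07), Fancd2 from 82 ± 7.21 to 1401 ± 52.5 and the strand exchange protein gene Rad51 from 282 ± 15.7 to 1302 ± 19.9.

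Serine and one-carbon genes rose in 20 of 22 cases and fell in 1 (adjusted p = 2.58e-08). Mthfd2, a mitochondrial enzyme of the folate cycle (gene 17768, chromosome 6, 83305704 to 83317604), rose from 421 ± 12.1 to 9079 ± 28.6, which is 4.43 on the log2 scale (SE 0.03, adjusted p = 5.8e-30). The mitochondrial serine hydroxymethyltransferase Shmt2 rose from 2133 ± 61.3 to 26155 ± 135, and Psat1, of serine synthesis, from 2566 ± 72.5 to 24570 ± 171. The integrated stress response list, which shares 6 members with other lists, had 23 of 27 genes higher and 4 lower (adjusted p = 1.62e-08), among them asparagine synthetase, Asns (3.72, SE 0.02) and Trib3 (4.77, SE 0.03). In the methionine cycle, 16 of 22 genes rose and 4 fell (adjusted p = 0.00146), and the amino acid transporter Slc7a5 rose from 3027 ± 131 to 24214 ± 340. In the cholesterol list, 20 of 22 genes rose and 1 fell (adjusted p = 2.15e-07), with Fdps, farnesyl diphosphate synthase, at 1537 ± 38.2 and 5897 ± 12.7 in shCTR and shp53.

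Which R-loop factors changed is of interest because the series title names R-loops. Among these genes, 23 of 30 rose and 6 fell (adjusted p = 0.00139, but adjusted p = 0.232 with an estimated correlation). The DNA helicase gene Pif1 rose from 23.7 ± 3.51 to 1231 ± 6.51 and the RNA helicase gene Ddx21 from 4300 ± 107 to 11931 ± 208, whereas the topoisomerase gene Top3b fell from 6046 ± 113 to 2394 ± 71.1. Glycolysis (16 rose and 3 fell of 20, adjusted p = 0.0014) and the tricarboxylic acid cycle (18 and 2 of 23, adjusted p = 0.00102) passed at the preset correlation, with adjusted p = 0.15 and 0.0715 with an estimated correlation. NF-kB and inflammatory genes fell in 19 of 28 cases and rose in 5 (adjusted p = 0.0384, with an estimated correlation adjusted p = 0.238, and after quantile normalization 0.0772). The cytokine gene Lif, for example, fell from 6980 ± 142 to 927 ± 31.6.

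The 6 largest increases without treatment were in Soat2, which esterifies cholesterol (3.67 ± 1.53 to 880 ± 88.5), Cth, an enzyme of transsulfuration (1.67 ± 2.89 to 169 ± 22.5), the hormone gene Fgf21 (2.33 ± 2.52 to 215 ± 9.64), Mef2b (1 ± 1 to 131 ± 14.9), Pif1 and Vgf (54.7 ± 10.7 to 2503 ± 29.7). The 6 largest decreases were in Cpz (1977 ± 12.2 to 2.33 ± 1.15), Ces2e (494 ± 23.7 to a listed 0 in all replicates), the death receptor gene Fas (545 ± 55 to 1.67 ± 0.577), Anxa8 (6866 ± 79.7 to 57.3 ± 3.21), Podn (173 ± 12.8 to 0.667 ± 0.577) and Ptprv (1448 ± 30.7 to 12.7 ± 3.79).

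Of 14297 genes tested, limma called 11779 in this comparison, 5788 higher and 5991 lower in shp53, and 1901 and 2044 of them changed at least 2-fold. Adjusted over the list alone, the serine and one-carbon count was 21 higher and 1 lower, and the counts of the other lists given so far were the same. The lists not called included germline genes (5 higher and 6 lower of 31, adjusted over the list alone 5 and 4), imprinted genes (4 and 9 of 24, alone 4 and 8), interferon (4 and 17 of 33, alone 4 and 16, adjusted p = 0.0784), antigen presentation (5 and 10 of 16), heterochromatin (22 and 10 of 34, adjusted p = 0.0784) and epithelial genes (2 and 10 of 18, adjusted p = 0.0673, and 0.0497 when scaled to equal totals). By fry, each of these lists passed, from adjusted p = 3.45e-10 for epithelial genes to 0.000934 for germline genes. For germline genes the balance turned after quantile normalization (5 and 2). Scaled to equal totals, the split of all genes turned to 6068 higher and 5679 lower. Most calls were changes of less than 2-fold, and the direction of the smallest of them depends on the scaling.

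**Figure D2:**
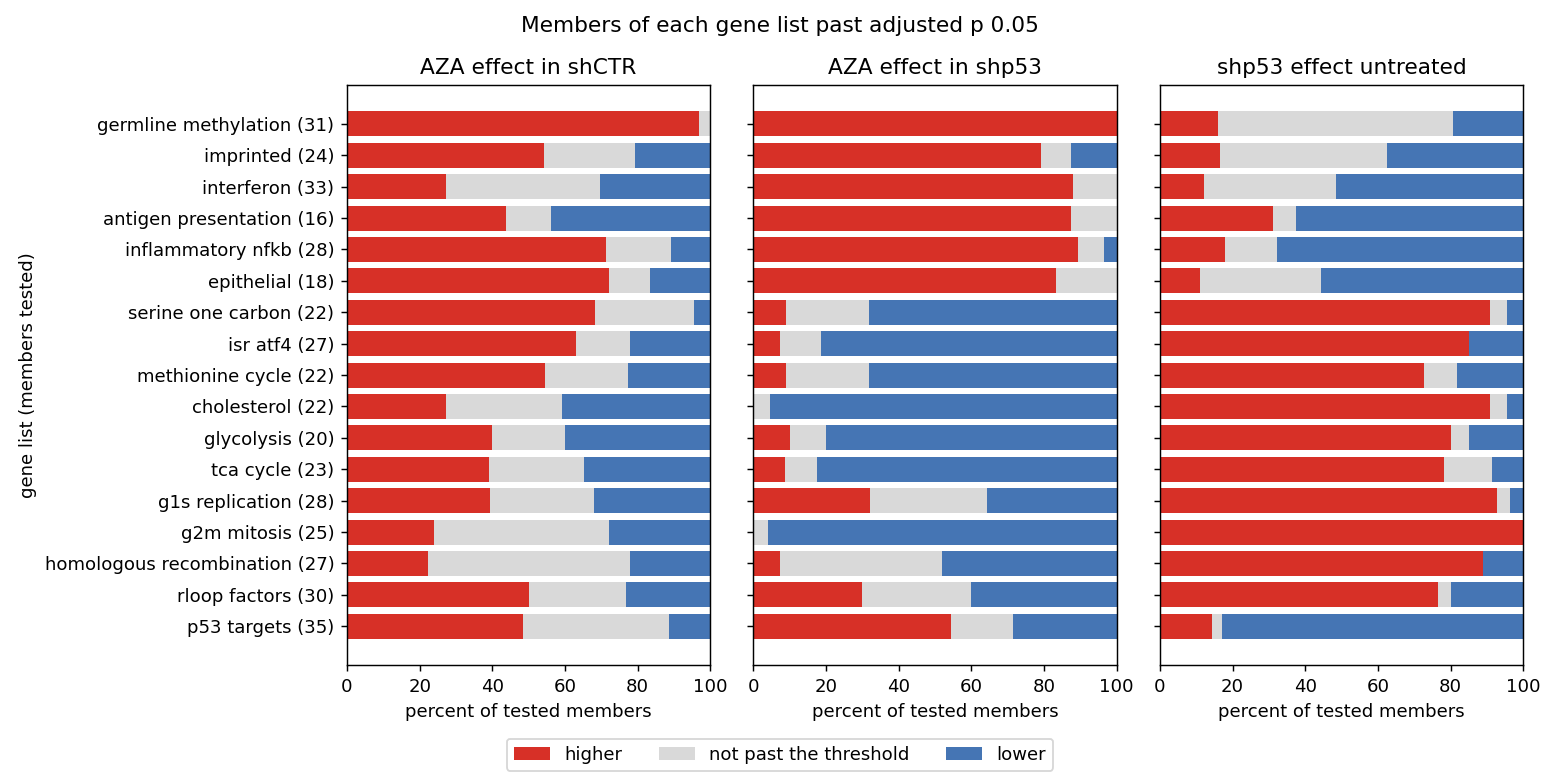
Percent of tested members (x axis) of 17 gene lists (y axis, members tested in brackets) that were higher (red), lower (blue) or not past an adjusted p of 0.05 (gray) in 3 contrasts. Serine and one-carbon genes were higher with AZA in shCTR (15 of 22), lower with AZA in shp53 (15 of 22) and higher in untreated shp53 (20 of 22).

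The next comparison asked what AZA changed in cells with p53. Genes silent in untreated cells were switched on, germline genes among them, and large decreases were few. Of the germline genes, 30 of 31 rose, and 31 when adjusted over the list alone (camera adjusted p = 1.82e-14). The list held 38 genes, of which 31 were tested. A gene silent without AZA was tested only where AZA raised its mean to 10, so the filter itself favoured members that rose. Dazl, a germ cell RNA-binding protein gene (gene 13164, chromosome 17, 50279394 to 50293599), was listed at 0 in all untreated replicates and reached 219 ± 18.7. Taf7l, a testis paralog of a general transcription factor subunit, was likewise listed at 0 and reached 328 ± 14.7, and Tex19.1 went from 0.333 ± 0.577 to 223 ± 9.07. Rhox5, an X-linked homeobox gene of the reproductive tract, was already present and rose from 205 ± 9.61 to 2145 ± 98.5 (log2 3.38, SE 0.04).

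Serine and one-carbon genes rose in 15 of 22 cases and fell in 1 (adjusted p = 2.32e-05), Mthfd2 from 421 ± 12.1 to 1373 ± 37.3 and Psat1 from 2566 ± 72.5 to 5288 ± 149. Integrated stress response genes rose in 17 of 27 cases and fell in 6, or 7 adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.1 with an estimated correlation). NF-kB and inflammatory genes rose in 20 of 28 cases and fell in 3, or 21 and 4 adjusted over the list alone (adjusted p = 0.000167, and adjusted p = 0.1 with an estimated correlation). The chemokine gene Ccl2 rose from 297 ± 22.7 to 2992 ± 74.9 and Tnfaip3, which restrains NF-kB signalling, from 383 ± 9.17 to 2043 ± 42. Epithelial genes rose in 13 of 18 cases and fell in 3, or 14 and 3 adjusted over the list alone (adjusted p = 0.00135, and adjusted p = 0.117 with an estimated correlation). The keratin gene Krt19 rose from 7562 ± 100 to 17190 ± 274 and Grhl2, an epithelial transcription factor gene, from 3.67 ± 1.53 to 278 ± 24.3.

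Interferon genes had no clear direction, with 9 of 33 higher and 10 lower (adjusted p = 0.822), but 5 higher and 18 lower after quantile normalization (median log2 fold change -0.42, adjusted p = 0.112). Stat1 fell from 793 ± 32.3 to 528 ± 14.6. The p53 targets gave 17 higher and 4 lower of 35 (adjusted p = 0.107, but 0.00445 after quantile normalization), with Cdkn1a at 24772 ± 542 and 24932 ± 174, Gdf15 at 14.7 ± 4.51 and 261 ± 2.65 and Btg2 at 31626 ± 156 and 22583 ± 244 without and with AZA. Other lists that camera did not call included G1/S (11 higher and 9 lower of 28), G2/M (6 and 7 of 25), the methionine cycle (12 and 5 of 22), the DNA methylation machinery (4 and 7 of 18), heterochromatin (7 and 18 of 34, adjusted p = 0.0845), R-loop factors (15 and 7 of 30) and homologous recombination (6 and 6 of 27). Imprinted genes, at 13 higher and 5 lower of 24 (14 and 5 adjusted over the list alone), were not called either, and after quantile normalization their counts were 6 and 5, with a median log2 fold change of -0.02. Nor did camera call mesenchymal genes (8 and 8 of 19), glycolysis (8 and 8 of 20), the tricarboxylic acid cycle (9 and 8 of 23) or cholesterol genes (6 and 9 of 22). By fry, however, imprinted genes (adjusted p = 7.03e-07) and p53 targets (2.01e-08) passed, while G2/M (0.231) and mesenchymal genes (0.221) did not. Scaled to equal totals, the balance of higher and lower genes turned for G2/M (8 and 6) and cholesterol genes (7 and 5), and it became even for interferon genes. After quantile normalization it became even for G1/S, while G2/M leaned further lower (3 and 12). From an even count, homologous recombination and mesenchymal genes leaned lower after quantile normalization and higher with equal totals, and glycolysis genes leaned higher with both.

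Besides Taf7l and Dazl, the largest increases were in Uba1y, a Y-linked ubiquitin-activating enzyme gene (0.667 ± 0.577 to 604 ± 14), the cadherin gene Cdh19 (listed at 0, then 241 ± 14.6), the claudin gene Cldn6 (2.67 ± 1.53 to 812 ± 37) and Naa11 (listed at 0, then 197 ± 7.94). Reads of Uba1y and of its X-linked paralog are hard to separate, so its value is uncertain. The largest decreases were smaller: Chrd, a secreted antagonist of bone morphogenetic proteins (-1.87, SE 0.10), Lpar4 (-1.74, SE 0.14), Iigp1 (-1.66, SE 0.17), Fat4 (-1.64, SE 0.19), Tgfbi (-1.60, SE 0.07) and Pag1 (-1.57, SE 0.05).

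In this comparison limma called 8981 genes, 4709 higher and 4272 lower with AZA. This balance turned after quantile normalization, to 4251 higher and 5048 lower, and was 5409 and 3560 with equal totals. At least 2-fold, 1299 were higher and 169 lower, and at least 4-fold, 622 and 7. By levels alone, 40 genes went from a sum of at most 3 over the replicates to a mean of at least 50. Counts adjusted over the list alone were the same where no second count is given.

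In cells with the Trp53 hairpin, what did AZA change? Germline, interferon and antigen presentation genes rose, and genes of mitosis, cholesterol synthesis and the one-carbon pathway fell. All 31 germline genes tested, of 38 listed, rose (adjusted p = 1.06e-16), Dazl from a listed 0 to 894 ± 30.3 and Rhox5 from 606 ± 9.64 to 5937 ± 59.6. As in shCTR, the filter on low values favoured members that rose. Interferon response genes rose in 29 of 33 cases and the other 4 did not pass the test (adjusted p = 1.1e-09). Ifi27 (gene 52668, chromosome 12, 103434189 to 103440245) rose from 154 ± 10.6 to 1059 ± 42.5 (log2 2.77, SE 0.06), Ddx58, the RNA sensor RIG-I, from 579 ± 10 to 1573 ± 84.2, and Bst2, tetherin, from 709 ± 36.1 to 2120 ± 62.6.

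Antigen presentation genes rose in 14 of 16 cases (adjusted p = 1.47e-07), with Tap2, of the peptide transporter, going from 62 ± 7.21 to 317 ± 22.3 and the class I gene H2-K1, whose reads may be shared with related class I genes, from 3519 ± 66.6 to 6087 ± 82.5. In shCTR, H2-K1 rose more, from 608 ± 14 to 2165 ± 45.7, and the list was even, with 7 of 16 higher and 7 lower (adjusted p = 0.856). NF-kB and inflammatory genes rose in 25 of 28 cases and fell in 1 (adjusted p = 1.24e-11). The matrix metalloproteinase gene Mmp9 rose from 313 ± 6.81 to 5513 ± 119 and Ccl2 from 32 ± 7.81 to 1909 ± 45.1. Imprinted genes rose in 19 of 24 cases and fell in 3 (adjusted p = 1.17e-05), among them Grb10 (1 ± 1.73 to 423 ± 13.3) and Meg3 (0.333 ± 0.577 to 184 ± 12.2). Epithelial genes rose in 15 of 18 cases (adjusted p = 1.7e-06), the adhesion molecule gene Epcam from 15.7 ± 3.21 to 332 ± 6.66. The p53 targets rose in 19 of 35 cases and fell in 10 (adjusted p = 0.00582), with Cdkn1a up from 2889 ± 80.4 to 7010 ± 63, still below its level in shCTR. These rises, and the falls of the groups that follow, were in the libraries that were shallowest and had the highest mitochondrial share.

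Other lists fell. In G2/M and mitosis, 24 of 25 genes fell (adjusted p = 5.46e-07), the spindle factor gene Tpx2 from 6930 ± 15.9 to 3849 ± 90 and the kinase gene Aurka from 3935 ± 29.7 to 2513 ± 104. Of the cholesterol genes, 21 of 22 fell (adjusted p = 9.52e-09), such as Insig1 (-0.91, SE 0.03) and Fdps (-0.92, SE 0.03). Serine and one-carbon genes fell in 15 of 22 cases and rose in 2 (adjusted p = 0.00263), Shmt2 from 26155 ± 135 to 15461 ± 134 and the first enzyme of serine synthesis, Phgdh, from 11011 ± 287 to 7895 ± 104. Integrated stress response genes fell in 22 of 27 cases (23 adjusted over the list alone) and rose in 2 (adjusted p = 7.05e-07), Trib3 from 7378 ± 92.5 to 3390 ± 64.4 and the stress phosphatase subunit gene Ppp1r15a from 11886 ± 86 to 4517 ± 90.9. Methionine cycle genes fell in 15 of 22 cases and rose in 2 (adjusted p = 0.0022).

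Glycolysis genes fell in 16 of 20 cases and rose in 2 (adjusted p = 0.000915, but adjusted p = 0.101 with an estimated correlation and 0.0726 after quantile normalization). Their median log2 fold change was -0.24, while their mean was 0.10 because of the lactate transporter gene Slc16a3, which went from 0.667 ± 0.577 to 144 ± 14.8. Genes of the tricarboxylic acid cycle fell in 19 of 23 cases and rose in 2 (adjusted p = 0.000622, and 0.207 after quantile normalization). All 9 mitochondrially encoded genes tested rose (adjusted p = 0.000917, but adjusted p = 0.223 with an estimated correlation), ND4 from 41397 ± 2197 to 61190 ± 716. Lists not called included G1/S (9 higher and 10 lower of 28), the DNA methylation machinery (5 and 10 of 18), heterochromatin (7 and 20 of 34, adjusted p = 0.0537), R-loop factors (9 and 12 of 30), homologous recombination (2 and 13 of 27, alone 2 and 12) and mesenchymal genes (8 and 7 of 19). For G1/S, R-loop factors and the DNA methylation machinery the balance of higher and lower genes turned with the scaling. With equal totals it became even for heterochromatin and nearly even for homologous recombination (6 and 7). Heterochromatin passed when single libraries were left out (0.0423 without shp53_AZA replicate 1, 0.0457 without shp53_NT replicate 2 and 0.0482 without shp53_NT replicate 3).

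The largest increase was in Xist, the RNA that coats the inactive X chromosome (gene 213742, chromosome X, 103460373 to 103483233, minus strand), from 1.33 ± 0.577 to 2990 ± 304, where reads of the antisense gene Tsix cannot be told from it without a stated strand setting. Besides Dazl, the others were Tex19.1 (listed at 0, then 677 ± 16.4), Serpinb1c (0.667 ± 0.577 to 939 ± 38.9), the ribosomal protein paralog Rpl39l (listed at 0, then 578 ± 29.5) and Dpep3 (0.667 ± 0.577 to 816 ± 23.3). The largest decreases were in Ptprt (106 ± 5.29 to 15.3 ± 2.89), Pclo (1009 ± 71.5 to 220 ± 14.8), the ATP-gated channel gene P2rx3 (2695 ± 78.1 to 669 ± 15), Acot2 (575 ± 15 to 143 ± 5.29), Angptl6 (948 ± 7.57 to 242 ± 15) and Extl1 (352 ± 30.6 to 94.3 ± 15).

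Here limma called 10286 genes, 4795 higher and 5491 lower. Scaled to equal totals, which shifts the median gene by 0.1 on the log2 scale, the split was 6176 higher and 3940 lower, so the direction of small changes depends on the scaling. At least 2-fold, 1974 were higher and 172 lower. From a sum of at most 3 to a mean of at least 50, 136 genes were switched on. Counts adjusted over the list alone were the same where no second count is given.

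Did AZA act differently in shp53 and shCTR? The interaction tests this difference directly. It passed for 8611 of 14297 genes, with a higher AZA effect in shp53 for 4135 and a lower one for 4476, a balance that turned to 4811 and 3737 when scaled to equal totals. Interferon genes had a higher AZA effect in shp53 in 30 of 33 cases and a lower one in 1 (adjusted p = 2.58e-10), Ifi27 by 2.65 (SE 0.08) and Irgm1 by 1.74 (SE 0.08). Irgm1 started lower in shp53 (273 ± 17.5, and 908 ± 6.35 in shCTR) and reached similar levels under AZA (700 ± 29.5 and 694 ± 39.4). Higher effects in shp53 were also found for germline genes (21 of 31, adjusted p = 3.52e-05), antigen presentation (13 higher and 2 lower of 16, adjusted p = 6.17e-05), imprinted genes (18 and 2 of 24, 19 and 2 adjusted over the list alone, adjusted p = 0.000118) and NF-kB and inflammatory genes (18 and 3 of 28, 19 and 3 adjusted over the list alone, adjusted p = 9.72e-07). Among these, the germ cell helicase gene Ddx4 differed by 2.64 (SE 0.27), B2m, the light chain of class I molecules, by 0.81 (SE 0.03), the imprinted RNA H19 by 3.38 (SE 0.22) and Mmp9 by 2.76 (SE 0.07). Against the antigen presentation list, H2-K1 differed by -1.04 (SE 0.04). Fibroblast markers (8 of 11 higher, adjusted p = 0.000357) and mitochondrially encoded genes (6 of 9, adjusted p = 0.00105, but adjusted p = 0.25 with an estimated correlation) were called in the same direction.

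The AZA effect was lower in shp53 for 18 of 22 serine and one-carbon genes, with 2 higher (adjusted p = 1.58e-07), for 21 of 27 integrated stress response genes, with 5 higher (adjusted p = 2.58e-10), and for 15 of 22 methionine cycle genes, with 1 higher (adjusted p = 9.02e-05). Mthfd2 differed by -1.92 (SE 0.04), Trib3 by -2.58 (SE 0.05) and Slc7a5 by -0.94 (SE 0.04). Rising in shCTR and falling in shp53 was the pattern of 12 one-carbon, 16 stress response and 8 methionine cycle genes. Cholesterol genes (21 of 22 lower, adjusted p = 8.13e-10) and G2/M genes (22 of 25 lower, adjusted p = 9.72e-07) followed, for instance Hsd17b7 (-1.04, SE 0.04) and Ube2c (-0.91, SE 0.06). Glycolysis (14 lower and 3 higher of 20, adjusted p = 0.000383, but adjusted p = 0.0981 with an estimated correlation) and the tricarboxylic acid cycle (13 of 23 lower, adjusted p = 0.000383) were lower as well. Lists not called included p53 targets (13 higher and 13 lower of 35), G1/S (5 and 11 of 28), R-loop factors (5 and 11 of 30), homologous recombination (1 and 10 of 27, adjusted p = 0.0802), the DNA methylation machinery (5 and 6 of 18), heterochromatin (10 and 12 of 34), mesenchymal genes (8 and 7 of 19) and epithelial genes (9 and 2 of 18, adjusted p = 0.0598). The balance turned under both scalings for the DNA methylation machinery (6 and 5 after quantile normalization, 7 and 6 with equal totals) and heterochromatin (12 and 9, 12 and 10), and p53 targets leaned higher with equal totals (15 and 10). Epithelial genes passed when single libraries were left out (0.0387 without shp53_NT replicate 2, 0.0488 without shCTR_NT replicate 3 and 0.0447 without shCTR_AZA replicate 3).

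**Figure D3:**
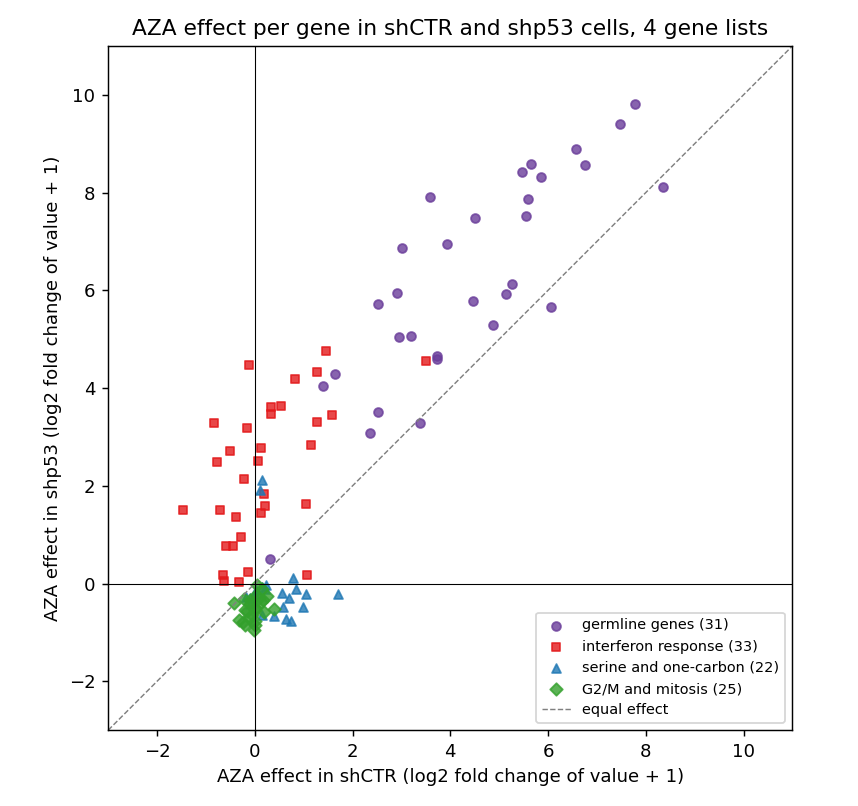
AZA effect as log2 fold change of value + 1 in shCTR (x axis) and in shp53 (y axis) for the tested members of 4 gene lists, 1 point per gene; the dashed line marks equal effects. Most interferon genes lie above the line (higher AZA effect in shp53 for 30 of 33), while one-carbon genes lie mainly to the lower right of the origin (12 rose in shCTR and fell in shp53).

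Across genes, the AZA effects in shCTR and shp53 correlated at r = 0.752, where genes are not independent replicates. The 2531 genes that rose and the 2597 that fell in both compare with 1579 and 1641 for independent lists, and scaled to equal totals 1691 fell in both. In opposite directions, 1202 rose in shCTR and fell in shp53 and 718 did the reverse, fewer than the 1809 and 1433 for independent lists. A total of 108 genes had a sum of at most 3 in each untreated group and a mean of at least 50 in a treated one. Of these, 101 were higher and 2 lower in shp53_AZA than in shCTR_AZA, with a median log2 ratio of 1.76 (quartiles 1.31 and 2.61).

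Under AZA, how did shp53 differ from shCTR? The p53 targets stayed low (29 of 35 lower and 4 higher, adjusted p = 1.71e-11), with Mdm2 at 45190 ± 380 in shCTR_AZA and 4454 ± 98.1 in shp53_AZA. G2/M (all 25 higher, adjusted p = 2.61e-15), G1/S (27 of 28 higher, adjusted p = 6.78e-10) and homologous recombination genes (24 higher and 3 lower of 27, adjusted p = 3.98e-07) were still higher in shp53, such as Top2a (3.35, SE 0.03). So were serine and one-carbon genes (18 higher and 1 lower of 22, adjusted p = 3.08e-07), the integrated stress response (22 and 5 of 27, adjusted p = 7.9e-07) and cholesterol genes (16 and 5 of 22, adjusted p = 0.00133), with Mthfd2 at 1373 ± 37.3 and 7798 ± 58.1.

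Germline genes (29 of 31 higher, adjusted p = 0.000345) and interferon genes (27 higher and 2 lower of 33, adjusted p = 0.00279) were higher in shp53 here. The piRNA pathway gene Piwil2 stood at 154 ± 6.66 in shCTR_AZA and 435 ± 24 in shp53_AZA, and Bst2 at 547 ± 13.8 and 2120 ± 62.6. R-loop factors gave 21 higher and 6 lower of 30 (adjusted p = 0.00524, but adjusted p = 0.299 with an estimated correlation), with Fancd2 at 107 ± 7.55 and 1179 ± 48.1. Fancd2 was also given above for homologous recombination, so these 2 lists are not separate results. Lists not called included imprinted genes (16 higher and 5 lower of 24, adjusted p = 0.16), the methionine cycle (14 and 6 of 22, adjusted p = 0.0804), NF-kB and inflammation (14 and 9 of 28), antigen presentation (9 and 5 of 16) and epithelial genes (6 and 7 of 18). Heterochromatin (21 and 8 of 34, adjusted p = 0.0804), glycolysis (10 and 7 of 20, adjusted p = 0.341) and the tricarboxylic acid cycle (15 and 6 of 23, adjusted p = 0.107) were not called but passed after quantile normalization (0.0173, 0.00844 and 0.0046), and heterochromatin and the tricarboxylic acid cycle also passed with equal totals (0.0388 and 0.0274).

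The largest increases under AZA were in the receptor gene Edar (0.333 ± 0.577 to 172 ± 17), Fgf21 (2.67 ± 2.89 to 357 ± 15.2), the basement membrane gene Nid2 (2.33 ± 0.577 to 254 ± 11.8), Bcl6b (4.33 ± 2.52 to 293 ± 23.3), the imprinted gene Dlk1 (1.67 ± 2.08 to 123 ± 3.79) and Adm2 (2.67 ± 0.577 to 204 ± 12.7). The largest decreases were in Ces2e (769 ± 6.51 to 0.333 ± 0.577), Ano3 (462 ± 16.8 to 0.333 ± 0.577), Podn (223 ± 15.6 to 0.667 ± 0.577), Sec14l5 (302 ± 26 to 2 ± 2), Cpz (2949 ± 99 to 32.3 ± 16.9) and Stox2 (309 ± 22 to 4.33 ± 5.86). In all, limma called 11694 genes, 6123 higher and 5571 lower, of which 2158 and 1343 changed at least 2-fold. After quantile normalization the split turned to 5937 higher and 6069 lower. The shp53 effects with and without AZA shared 4612 higher and 4608 lower genes, against 2479 and 2335 for independent lists (r = 0.745 across genes). Counts adjusted over the list alone were the same for every list given for this comparison.

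The shp53 effect without treatment and the AZA effect in shCTR were both taken against shCTR_NT. They shared 2508 higher and 2645 lower genes, where independent lists give 1906 and 1790 and simulated unchanged groups give 0. Their fold changes correlated at r = 0.137 across genes (0.503 in the simulation, over 20 runs), with a covariance of 0.142 (0.0152 in the simulation). The simulation held no changed gene, so its 0 shared genes and its r follow from its setting and cannot be set against these data. Noise in the shared control libraries gave only a small part of the covariance. Part of the excess of shared genes may still come from these libraries.

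The authors' deposited comparisons called 7626 genes for AZA in shCTR, 9216 for AZA in shp53, 11092 for shp53 untreated and 11141 for shp53 under AZA. For AZA in shp53 their balance was the reverse of the one given here, with 4962 higher and 4254 lower, and for shp53 under AZA it was nearly even (5578 and 5563). Both sources called 7498, 8664, 10856 and 10720 genes. No gene that limma called had the opposite sign in the deposited fold changes, which were 0 for 1 gene in each comparison that involves shp53_AZA. The median difference of the deposited log2 fold changes from those given here was 0.042 and -0.041 in these comparisons, and its cause was not tested.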

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

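The results in this part come from the interaction, which was fixed before the data were examined. The tests of mixed cells and of fibroblasts, and scaling to equal totals, were chosen after the results were seen.

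AZA effects that differ between shCTR and shp53 were found for 8611 genes, and 1920 of them changed significantly in opposite directions. Opposite changes were fewer than independent lists give (1202 and 718, against 1809 and 1433), so the 1920 are no excess. In 100 drawn assignments of the 12 samples to 4 groups, only the real one gave as many genes (8611, and 5037 for the highest of the others). The drawn groups mix hairpins and treatments, whose effects then enter the spread and lower the number of calls. The comparison therefore cannot show whether an interaction exists, and no conclusion is drawn from it. For the 4 comparisons of 2 groups, each fitted on its 6 samples alone, there are only 10 splits, too few for a share under 0.05. Of these 10, 1 split (the real one) gave as many genes in each comparison, with 8777, 10144, 11386 and 11732 genes for AZA in shCTR, AZA in shp53, shp53 untreated and shp53 under AZA, and the highest other split gave 0 by limma.

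At the level of lists, 14 had an AZA effect that differs between shCTR and shp53. By camera's adjusted p these were interferon (2.58e-10), the integrated stress response (2.58e-10), cholesterol (8.13e-10), serine and one-carbon (1.58e-07), G2/M (9.72e-07), NF-kB and inflammation (9.72e-07), germline (3.52e-05), antigen presentation (6.17e-05), methionine cycle (9.02e-05), imprinted (0.000118), fibroblast markers (0.000357), glycolysis (0.000383), tricarboxylic acid cycle (0.000383) and mitochondrially encoded genes (0.00105). With an estimated correlation, glycolysis (adjusted p = 0.0981) and mitochondrially encoded genes (adjusted p = 0.25) were no longer called.

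Among single genes, the interaction was largest upward for Grb10 (adjusted p = 6.8e-11), Nid2 (5.22e-09), Slc16a3 (2.39e-06), Rian (9.63e-08), Meg3 (2.27e-08) and Syce2 (3e-06). AZA took Grb10 from 21 ± 5 to 37.7 ± 3.51 in shCTR and from 1 ± 1.73 to 423 ± 13.3 in shp53. The imprinted RNAs Rian and Meg3, which are neighbours, reached 7 ± 2.65 and 3.67 ± 0.577 in shCTR_AZA and 131 ± 14.2 and 184 ± 12.2 in shp53_AZA. Syce2, of the meiotic synaptonemal complex, reached 6 ± 4.36 and 138 ± 18.9. It was largest downward for Myh7b (3.04e-07), Soat2 (2.58e-11), Ptprt (3.45e-07), Ano3 (5.44e-07), Hoxb9 (3.84e-08) and Tigit (1.6e-12). Myh7b went from 4 ± 3.61 to 285 ± 7.51 with AZA in shCTR and from 2.33 ± 0.577 to 9.67 ± 2.52 in shp53, Hoxb9 from 8.67 ± 4.04 to 55 ± 4.58 and from 195 ± 9.02 to 134 ± 18.3, and the immune receptor gene Tigit from 38.7 ± 6.51 to 154 ± 7.23 and from 248 ± 19.2 to 113 ± 5.69.

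The stronger AZA response of interferon and germline genes in shp53 was weighed against scaling and against the detection floor. The fewer of both scalings left 29 of 33 interferon genes with a higher AZA effect in shp53 past the threshold, and a pseudocount of 5 left 31, against 30 as reported. For interferon genes, neither explanation thus accounts for the number past the threshold. Its size did depend on scaling: their median interaction was 2.03 as reported and 1.55 after quantile normalization. Germline genes numbered 21 of 31 under both scalings, but 27 with the pseudocount of 5, and no bound had been set for them. Their count thus moved with the pseudocount, and no conclusion is drawn for them. The filter on low values, which favoured germline genes that rose, was not weighed here. The shallower depth of the shp53_AZA libraries would lower rather than raise detection. A biological difference may underlie the stronger response, such as more cell divisions and so more drug incorporated without p53, or another difference between shCTR and shp53 cells, but neither was tested.

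For the opposite AZA response of serine and one-carbon genes, scaling and shCTR cells mixed into the shp53_AZA libraries were weighed: under scaling to equal totals, 15 of 22 genes had a lower AZA effect in shp53, exactly the bound, which was written before that test was run, with medians of 0.35 in shCTR and -0.11 in shp53, while quantile normalization gave 16, 0.27 and -0.15. The median interaction of the list was -0.71, whereas equal totals move the interaction of the median gene by 0.057, which argues against scaling as the whole cause. A share of shCTR RNA that explains the fall would be 38.0% at the median of 14 genes (quartiles 17.6% and 44.9%), taken from the fallen genes whose level was more than 25% higher in shp53_NT than in shCTR_AZA, a restriction also added after seeing the data. The 85 abundant genes at least 4-fold lower in untreated shp53 allow 12.3% at their upper quartile, and Trp53 allows 1.86%, which argues against mixing as the whole cause. A response of the metabolic program that depends on p53, on its high starting level in shp53 or on another difference between the cells may remain, as a hypothesis that was not tested.

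The rise of fibroblast markers after AZA was weighed against fibroblasts among the treated shp53 cells. Of the abundant fibroblast transcripts Col1a1, Col1a2, Col3a1, Dcn and Lum, 1 fell, Col3a1 from 73091 ± 265 to 45356 ± 469, while Col1a1 rose from 120 ± 8.5 to 3802 ± 57.7. The high baseline of Col3a1 in untreated cells would hide a small share of fibroblasts. But Col1a2, which fibroblasts express together with Col1a1, reached only 63.3, Dcn 25 and Lum 63.3 (from 3.3, 4.7 and 6.7), which argues against fibroblasts as the source of Col1a1. Activation within the cultured cells may account for it and was not tested.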

How the results depend on the processing

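Scaling to equal totals and both scalings for the gene lists were chosen after seeing the data; the other settings were planned. Requiring an absolute log2 fold change of at least 1 lowered the calls to 1468 for AZA in shCTR, 2146 for AZA in shp53, 3945 for shp53 untreated, 3501 for shp53 under AZA and 1714 for the interaction, since that setting removes small changes by construction. Every other setting kept these 5 counts within 1.5 times. Leaving out each library gave 8377 to 9064, 9817 to 10392, 11501 to 11781, 11335 to 11755 and 8212 to 8477 calls, a log2 fold change of Trp53 between -2.46 and -2.42, and 57 to 59 called pairs of list and contrast (57 as reported, of 125). With an estimated correlation 45 pairs were called, with quantile normalization 58, and with equal totals 60. Of the 57, 44 were called the same way in every setting run. Named genes were mostly chosen for a small adjusted p or a large change, and all their 527 pairs of gene and contrast passed as reported. Their stability therefore does not carry over to other genes. Of these 527 pairs, 512 passed the same way in every setting run. After quantile normalization 2 reversed: Kdr for AZA in shCTR (-0.083, adjusted p = 0.825) and Col3a1 for shp53 untreated (0.062, adjusted p = 0.069), both no longer past the threshold, and the cause was not tested. The scalings shift the median gene by at most 0.1 on the log2 scale. Quantile normalization moved some list medians much further. For AZA in shp53 they went from 2.78 to 1.27 for imprinted, from 2.48 to 1.34 for interferon and from 2.26 to 0.91 for epithelial genes. The median of serine and one-carbon genes moved little, from -0.21 to -0.15. Genes that fell with AZA in both shCTR and shp53 numbered 1691 with equal totals, compared with 2597.

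Replicate numbers are shared between groups in the labels, but they gave no clear pairing of the samples. Deviations of samples with the same number correlated between -0.047 and 0.097, and 6 of 12 samples correlated best with their own number. No such range was taken for samples with different numbers, so a weak pairing stays open. With the replicate number as a block, calls numbered 8960, 10263, 11765, 11688 and 8585 in the order above, Trp53 stood at -2.44, and 57 list pairs were called. The deposited table holds no interaction, so that alternative gave no value for it, and the fit on only the samples compared is the reported one for the interaction. Depth limits genes near 0, where a listed 0 does not show absence.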

Other observations

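The tests of X-linked genes and of histone genes were chosen after the results were seen. The marker lists were fixed before the data were examined.

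Markers of other cell types were measured in all groups. With AZA in shp53, 9 of 11 fibroblast markers rose and 1 fell (camera adjusted p = 0.00185), and in shCTR 5 rose and 4 fell (adjusted p = 0.856), an even split after quantile normalization. Col1a1, a chain of type I collagen, rose from 192 ± 23.1 to 2367 ± 23.8 in shCTR, and Thy1 went from 0.333 ± 0.577 to 153 ± 36.7 in shp53. Of 5 leukocyte markers tested, 4 rose with AZA in shCTR, and in shp53 3 rose and 1 fell (adjusted p = 0.12 and 0.178). After quantile normalization 2 rose and 2 fell in shp53. Fcer1g, for example, went from 7.33 ± 2.08 to 72 ± 4.36 in shp53. Of 4 endothelial markers, 3 rose and 1 fell in each (adjusted p = 0.107 and 0.0708). Kdr, which rose in both, had a negative fold change in shCTR after quantile normalization. Cdh5, a cadherin of endothelial junctions, rose from 13.3 ± 1.15 to 693 ± 49.1 in shp53. Acinar markers were scarce, with 5 of 18 tested, of which 1 fell with AZA in shCTR, and in shp53 2 rose and 1 fell (adjusted p = 0.822 and 0.487). After quantile normalization 3 fell in shCTR, and in shp53 1 rose and 3 fell. Their most abundant tested member, the elastase gene Cela1, stood at 352 ± 11.9 in shCTR_AZA and 361 ± 34.4 in shp53_AZA.

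In both shp53 effects, transcripts of histone genes ran against the other proliferation genes. All 23 tested Hist genes fell in untreated shp53, with a median log2 fold change of -3.56 (camera adjusted p = 2.65e-06), and all 23 were lower under AZA, with a median of -3.13 (adjusted p = 2.45e-06). With an estimated correlation, both had adjusted p = 0.00163. The camera p-values of this family were adjusted over the 5 contrasts, not over the gene lists. With AZA, 8 of the 23 fell and none rose in shCTR (adjusted p = 0.0224, and 0.0431 with an estimated correlation), and in shp53 3 rose and 5 fell (adjusted p = 0.778). Most histone messages lack a poly(A) tail and the library kit selects polyadenylated RNA, so the values may reflect polyadenylated forms alone. The copies are also similar in sequence, so their reads cannot be assigned with certainty.

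X-linked genes rose more often with AZA than autosomal genes. At least 2-fold, 69 of 452 X-linked genes (15.3%) rose in shCTR compared with 1226 of 13826 autosomal genes (8.9%), an odds ratio of 1.85 (Fisher's exact test, two-sided, p = 1.82e-05, adjusted over both tests 3.64e-05). In shp53, 77 (17%) rose compared with 1892 (13.7%), an odds ratio of 1.3 (exact p = 0.0444, adjusted 0.0444), which is close to the threshold. The Fisher test counts each gene as independent, although genes are not independent replicates, so both p-values may be too small. The presence of many germline genes on the X chromosome is a candidate explanation, which the test does not single out. Xist, which coats a silenced X chromosome, was near 0 before treatment, at 4.33 ± 2.08 in shCTR_NT and 1.33 ± 0.577 in shp53_NT, and rose to 820 ± 51.6 in shCTR_AZA. These levels give no support for a coated X chromosome in untreated cells, and reactivation was not tested.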
